A study of Oryza sativa with 13 samples.

How the data were processed

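RNA from 9 rice tissues was hybridised to the Affymetrix rice 57K array, on 13 arrays of 5 ug total RNA each per the labels. The deposited values are 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes they came from GCOS and MAS5, whose versions, detection thresholds and filters are not given in the sources used here. The deposited table holds no detection calls, and every array had a 2% trimmed mean between 500.06 and 500.08, so the intensities were used without further scaling. Arrays were put in 9 groups from their titles, with 3 stigma arrays, 3 ovary arrays and 1 array in each of the 7 other groups.

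The test designs, the alternatives, 30 gene lists and the rule for naming genes were set before the data were examined. M, the median of all values in the table, was 64.3. Intensities were taken to log2 after adding a pseudocount of 6.43 (0.1 times M). A probe set was kept when the mean of at least 1 group was at or above M, which left 43055 of 57258 after 123 control probe sets had been left out. A mean per group was fitted with limma 3.58.1 in R 4.3.3, with contrasts of stigma against each other tissue and empirical Bayes moderation with an intensity trend. Residual degrees of freedom were 4, all from stigma and ovary, and the median prior degrees of freedom were 3.73. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and a fold of at least 2. Stigma-preferential probe sets passed this in all 8 contrasts with a higher value in stigma, and ovary-preferential ones the same for ovary.

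Probe sets were named with pandas 2.3.3 from the array's annotation table joined by gene number to the gene table of assembly ASM3414082v1, none of whose coordinates were used. Exactly 1 gene was given for 22436 probe sets, several for 95 and none for 34727. The 17905 genes reached included 2457 with a symbol beyond a locus number. Named genes have exactly 1 gene per probe set and such a symbol, and a gene with several probe sets is shown by the one with the highest mean log2 value. For stigma against ovary they are the 14 largest rises and 12 largest falls among calls whose stigma and ovary values did not overlap. The rule further takes the 16 stigma-preferential genes with the largest smallest-of-8 log2 fold change, 3 rises and 3 falls for each lone tissue, up to 4 passing members of each list (or the 2 brightest where none passed), and all floral organ identity genes.

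Gene lists were tested for stigma against ovary with limma's camera at a preset correlation of 0.01, and by Fisher's exact test among stigma-preferential genes with all 17640 kept genes as background, for lists with at least 5 measured genes. The tables held symbols and no descriptions, so only 15 of the 30 lists, which searched mostly for descriptions, matched a measured gene, and 12 had at least 5. A further 36 lists were therefore drawn up from symbols, after the name tables were read and the range of the values was known, and before any single gene's expression values were seen. Camera results are given over the 12 lists and over all 48. The symbol lists share genes with the fixed lists, so the lists are not independent. Camera compares a list with all other genes, whose median log2 fold change between stigma and ovary was -0.13.

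The calls were tested on simulated data with the spread of the real arrays. Changed probe sets were drawn from those with a mean log2 value over log2 of M, so recovery of dimmer ones was not measured. They were also far fewer than the calls between stigma and ovary in the real data, so the adjusted threshold was not alike. Of 50 changed probe sets at each size, the stigma and ovary contrast recovered 72% at 3-fold, 74% at 4-fold, 94% at 8-fold and 98% at 16-fold, with 1 false call among 43055 probe sets. The stigma-preferential rule recovered 72%, 60%, 88% and 92% of 25 at those folds with 0 false calls. Camera called 3 of 3 lists shifted by 0.5 in log2 and 0 of the others, in data without correlation between genes.

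Alternatives set beforehand were a pseudocount of 1 intensity unit and another of 0.5 times M, no filter and a filter at 2 times M, quantile normalization, scaling to the 75th percentile, moderation without trend, stigma arrays 2 and 3 averaged, a block for the replicate number, stigma and ovary arrays alone, each replicate left out, no fold minimum and a 4-fold minimum, an estimated correlation in camera, and folds without a test. After the data files were seen, the symbol lists and a stigma-preferential count without the endosperm, root or anther contrast were added, as was a choice of anther-preferential probe sets that left ovary aside. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. Probe-level files and a genome were not used here, so the match of probes to the current assembly was not examined.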

Results

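Transcript levels were measured on Affymetrix rice 57K arrays in 9 tissues of the japonica cultivar Nipponbare. The series' design text gives the aim as a profile specific to the stigma, the part of the pistil that receives pollen. Unpollinated stigmas and ovaries at anthesis, both from field-grown plants at 1 site, had 3 arrays each. Mature anther, 5-day seed, 10-day embryo and 10-day endosperm from another field site, shoot and root of 2-week seedlings from a growth chamber, and suspension-cultured cells had 1 array each. Each of the 13 arrays gave 57381 deposited intensities, and the number of arrays limits the precision. The 2% trimmed mean lay between 500.06 and 500.08 on every array. Across the 43055 probe sets kept, Pearson's r between arrays of the same tissue ran from 0.964 to 0.970, with probe sets not being independent replicates. The labels call stigma arrays 2 and 3 both biological replicate 2. They were used as separate samples, so that n = 3 for stigma rests on an assumption that the values do not settle. Arrays 2 and 3 correlated by 0.967, arrays 1 and 2 by 0.970 and arrays 1 and 3 by 0.966. The pair with the shared label was thus not the closest, but no known repeat arrays of 1 sample were at hand to compare. No label says that the 3 samples of a tissue came from separate plants, so p-values measure the spread between these samples only.

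Stigma and ovary are adjoining parts of 1 pistil, and the genes named for the largest rise in stigma included a potassium transporter gene, a defence gene and phenylpropanoid genes. HAK20, of the potassium transporter family, had an intensity of 3748 ± 661 in stigma and 7.67 ± 6.9 in ovary (SD, n = 3 each), a log2 fold change of 8.15 (SE 0.40, limma adjusted p = 2.51e-06). Its ovary level lay near the pseudocount of 6.43, so the size of the fold depends on it, with 9.04 for a pseudocount of 1 and 6.57 for 0.5 times the table median. PBZ1, a pathogenesis-related protein gene, had 4213 ± 414 in stigma and 21 ± 17.6 in ovary (7.58 in log2, SE 0.55, limma adjusted p = 1.71e-05). Os4CL2, a 4-coumarate:CoA ligase gene, measured 4725 ± 269.7 in stigma and 28.9 ± 21 in ovary (7.30 in log2). CHS1, for the chalcone synthase that starts flavonoid synthesis, measured 21746 ± 427 in stigma and 226 ± 71.1 in ovary (6.60 in log2). LOGL6, related to cytokinin-activating enzymes, measured 5290.0 ± 413 in stigma and 31 ± 18.7 in ovary (7.29 in log2). Where ovary values were near the background a single array moved the fold, as did the pseudocount, which at 0.5 times the table median moved 60 of 181 named folds against ovary by over 1.5 times. Without ovary replicate 2 PBZ1 had 6.82 and Os4CL2 6.68 in log2.

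Further genes with the largest rise over ovary were AT4 with a log2 fold change of 7.68, the chitinase gene Chib3H-a with 6.87, the aquaporin gene PIP1;3 with 5.36, the chitinase gene Rcb4 with 5.34 and the glutathione transferase gene GST-I with 5.26. EXLA4, an expansin-like gene, had 5.09, and the cytochrome P450 gene CYP71P1 had 4.96. CYP714D1, for a gibberellin-inactivating enzyme, had 4.95, and SAP2 had 4.78. AT4 had 7.04 without ovary replicate 2, and EXLA4 had 4.14 without ovary replicate 3.

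The genes named for the largest fall in stigma against ovary included genes of DNA replication and of chloroplasts. MCM4, a subunit of the replicative helicase, measured 2.37 ± 0.208 in stigma and 791 ± 224 in ovary, a log2 fold change of -6.47 (SE 0.22, limma adjusted p = 5.40e-07). Its stigma level lay under the pseudocount, and its fold was -7.84 with a pseudocount of 1 and -4.54 with 0.5 times the table median, where YAB2 had -5.60. YAB2, of the YABBY family of polarity factors, measured 47.8 ± 38.4 in stigma and 3531 ± 157 in ovary (-6.36 in log2). GLK1 and GLK2, transcription factors of chloroplast development, had -5.89 and -5.79 in log2, and CHLH, a subunit of the magnesium chelatase of chlorophyll synthesis, had -5.84. The chlorophyll-binding protein gene RCABP69 had -5.89, and the retinoblastoma-related gene Rbr1 had -5.43. UGE-1 had -5.80, with ovary values of 1095 ± 1167, and -4.95 without ovary replicate 3. TPP4 had -5.79, GLT2 -5.68, and the zinc finger gene C3H23 -5.47. Without stigma replicate 3 YAB2 had -5.64, RCABP69 -5.24 and C3H23 -4.88. Without stigma replicate 1 TPP4 had -6.41 and GLT2 -6.45, and GLT2 had -5.08 without stigma replicate 2. YAB2 read 86.3, 47.4 and 9.6 on stigma arrays 1, 2 and 3, and RCABP69 184.9, 130.2 and 35. CHLH, TPP4 and C3H23 fell in the same order, and MCM4, GLK1, GLK2, UGE-1, GLT2 and Rbr1 did not. Stigma arrays 1, 2 and 3 correlated with ovary array 1 by 0.889, 0.881 and 0.868. With the suspension cell array they correlated by 0.751, 0.746 and 0.739. The mature anther array was the only one of another tissue where the correlations did not fall in this order, with 0.748, 0.754 and 0.749. The cause of this order was not tested.

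Over all probe sets kept, 3799 were higher and 5620 lower in stigma than in ovary by at least 2-fold, 9419 in all and 40.3% of them higher. In 9388 of the 9419 the 3 stigma values lay on 1 side of the 3 ovary values, a state that 22850 of the 43055 probe sets showed where chance gives 10%. With stigma arrays 2 and 3 averaged into 1 sample, 3617 were higher and 5303 lower, 627 were higher in stigma than in all 8 other tissues, and 7 gene lists passed, with 1 list and 9 named genes losing their call. At the level of genes, 1996 were higher and 2899 lower of 17640. The share of higher calls depended on how the arrays were scaled. The 75th percentile was 452 to 464 on the stigma arrays and 539 to 539.9 on the ovary arrays, and scaling the arrays to it gave 5079 higher and 4431 lower, or 53.4% higher. Quantile normalization gave 4345 higher and 4735 lower, or 47.9% higher. The median log2 fold change of all probe sets was -0.09 as deposited and moved by 0.21 under 75th percentile scaling and by 0.10 under quantile normalization, so the fold changes here are relative to that uncertain zero. The actin 3' to 5' signal ratio, a sign of RNA quality, was 5.05 to 6.92 on the stigma arrays and 6.99 to 8.46 on the ovary arrays. Such ratios for other control genes did not share this order. GAPDH had 2.26 to 8.08 in stigma and 2.53 to 8.55 in ovary, and cyclophilin and elongation factor ratios overlapped as well. The ubiquitin ratio was higher in stigma, with 0.72 to 0.77 against 0.65 to 0.67 in ovary.

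**Figure D1:**
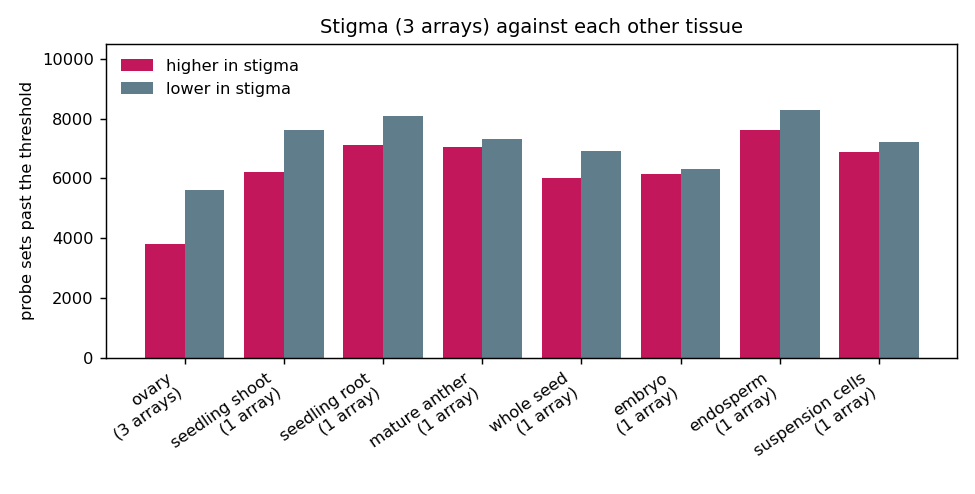
Bars give the number of probe sets past the threshold in stigma (3 arrays) against each other tissue, higher in stigma in red and lower in stigma in grey, on a linear axis from 0. Against ovary 3799 were higher and 5620 lower, and endosperm gave 7637 and 8298.

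Genes of the cell cycle and DNA replication were lower in stigma than in ovary. Among the lists fixed before the data were examined, 8 of 11 such genes fell and none rose, also 8 when adjusted over the list alone, with a median log2 fold change of -4.21. Besides MCM4, the cyclin gene CYCB2-2 measured 28.6 ± 11.9 in stigma and 1364 ± 535 in ovary, and the helicase subunit genes MCM3 and MCM2 had log2 fold changes of -4.81 and -4.76. The limma camera test over the 12 lists so fixed gave an adjusted p of 3.21e-04, and adjusted p = 0.0897 with an estimated correlation. A wider list, drawn from gene symbols before any expression value of a gene was seen, had 94 such genes with 50 lower, 5 higher and 39 not past the threshold (camera adjusted p = 1.21e-05 over 48 lists, and adjusted p = 0.486 with an estimated correlation). RPA1B and CYCA2-1 in it had log2 fold changes of -5.41 and -5.39. Of 12 meiosis genes, 5 were lower and none higher (camera adjusted p = 0.085), among them MEL1 with -1.58 and SHOC1 with -1.20. The meiosis list passed under 75th percentile scaling (adjusted p = 0.0471) and as deposited had an adjusted p of 0.407 with an estimated correlation, while SHOC1 no longer passed under either other scaling.

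Photosynthesis genes, which serve as shoot markers, were lower in stigma, with 12 of 21 lower, 1 higher and 8 not past the threshold and a median log2 fold change of -1.58. The chlorophyll-binding protein genes CAB2R and RCABP89 measured 643 ± 482 in stigma and 20935 ± 831 in ovary, and 172 ± 54.9 in stigma and 6800.5 ± 519.5 in ovary. CAB2R had a log2 fold change of -5.42, -6.02 without stigma replicate 1 and -4.59 without stigma replicate 3. On stigma arrays 1, 2 and 3 CAB2R read 1109.2, 672.3 and 147.2 and RCABP89 229.6, 165.5 and 120.4, a shared order whose cause was not tested. The camera test gave an adjusted p of 0.0102, and adjusted p = 0.407 with an estimated correlation. The polarity list with YABBY genes had 10 of 17 lower and 1 higher without passing (adjusted p = 0.114), and it passed under 75th percentile scaling (adjusted p = 0.0419). With an estimated correlation its adjusted p was 0.503 as deposited.

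Auxin genes were on balance higher in stigma than in ovary. Of 53 in the fixed list, 20 rose, 11 fell and 22 did not pass, and 21 rose and 11 fell when adjusted over the list alone. GH3-1, for an enzyme that conjugates auxin to amino acids, measured 10154 ± 384 in stigma and 533 ± 56.9 in ovary, a log2 fold change of 4.24. IAA31 and IAA12, of the Aux/IAA repressors of auxin response, measured 9188 ± 409.8 in stigma and 592 ± 139 in ovary, and 5062 ± 461 in stigma and 379.8 ± 110.4 in ovary, and GH3-8 had 3.87 in log2. The list had a camera adjusted p of 0.00399 over the 12 fixed lists, and adjusted p = 0.0897 with an estimated correlation. Of 25 Aux/IAA genes, 11 rose and 4 fell, IAA7 among the latter with -3.75 (camera adjusted p = 0.00986, and adjusted p = 0.272 with an estimated correlation), a call that ended under 75th percentile scaling (adjusted p = 0.0547).

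Expansins, proteins that loosen cell walls, were higher in stigma for 11 of 28 genes, lower for 2 and not past the threshold for 15. EXP6 measured 11841 ± 462 in stigma and 658 ± 38.9 in ovary, EXP2 had a log2 fold change of 3.53, and EXPB7 fell with -3.58. Anther-preferential genes were among the 11, namely EXPB9 (31286 in the anther, 1630.1 ± 922 in stigma and 317 ± 70.0 in ovary), EXPB10 and EXP26. The camera test gave an adjusted p of 0.0015, and adjusted p = 0.272 with an estimated correlation. Single heat shock protein genes moved in both directions, HSP16.9B measuring 403 ± 25.1 in stigma and 20.5 ± 2.45 in ovary, OSHSP17.3 rising by 3.35 in log2 and HSP26.2 falling with -1.26. Of 26 genes in the fixed heat shock and protein folding list, 7 rose and 1 fell, counts that were the same adjusted over the list alone (camera adjusted p = 0.0319 over the 12 fixed lists, and adjusted p = 0.371 with an estimated correlation). Over all 48 lists its adjusted p was 0.0479, a call that ended under quantile normalization (adjusted p = 0.0584) and 75th percentile scaling (adjusted p = 0.0885). In the symbol list 10 of 47 rose and 4 fell, with the factor gene Hsf-19 at -4.59, or -3.92 without stigma replicate 3 (adjusted p = 0.0145, and adjusted p = 0.272 with an estimated correlation).

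In all, 3 of the 12 fixed lists with at least 5 measured genes passed the camera test, and 8 of 48 passed with the 36 symbol lists added, 5 higher and 3 lower in stigma. With an estimated correlation, where the test has only 4 degrees of freedom, camera passed 0 of the 48, and 6 had an unadjusted p under 0.05. Splits of the same 6 arrays that mixed stigma and ovary gave 0 to 11 lists with the preset correlation, although each still set 2 stigma arrays against 1 and so is no measure of lists without a tissue difference. The directions of the 8 were the same under both other scalings. Fixed lists that did not pass, with the count adjusted over the list alone equal to that over all probe sets, were calcium signalling (7 higher and 5 lower of 37), small GTPases (3 higher and 4 lower of 17), defence proteins (2 higher and 1 lower of 6), AP2/ERF factors (2 higher and 1 lower of 18), WRKY factors (0 higher and 1 lower of 6), MYB factors (0 higher and 1 lower of 10), abscisic acid and dehydration (0 higher and 1 lower of 5), floral organ identity (2 higher and 2 lower of 7) and seed storage and starch (0 higher and 0 lower of 5). Another 3 had too few genes for a test and 15 matched no measured gene. Those 3 were aquaporins (0 higher and 0 lower of 3), cell wall loosening (1 higher and 0 lower of 1) and peroxidases and redox (0 higher and 2 lower of 3).

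**Figure D2:**
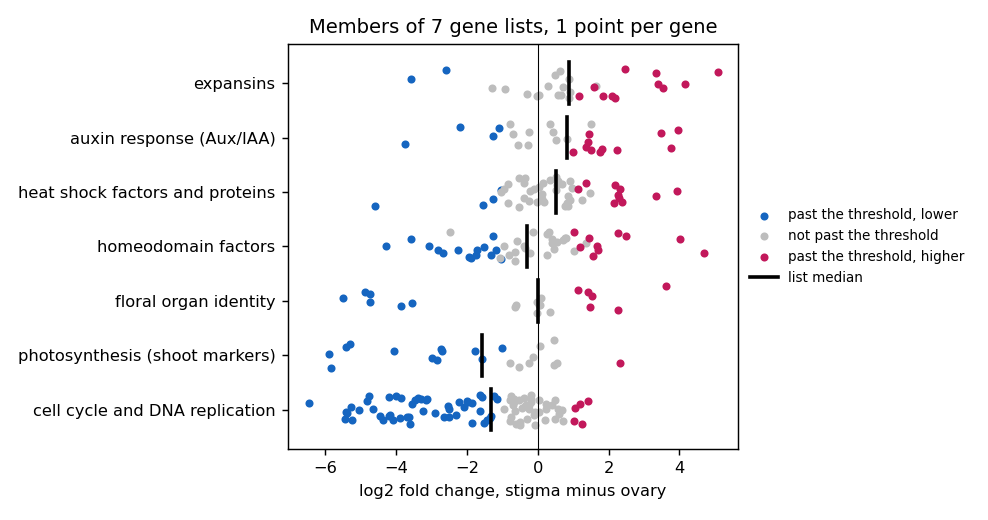
Each point is 1 gene of 7 symbol lists, placed by its log2 fold change of stigma minus ovary, with red and blue for genes past the threshold, grey for the others and a black bar at the list's median. The medians were -1.32 for cell cycle and DNA replication genes and 0.88 for expansins.

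Floral organ identity genes divided between the tissues, 6 of 20 being higher in stigma, 6 lower and 8 not past the threshold. The genes lower in stigma included the ovule identity gene MADS13 (213 ± 60.6 in stigma and 9707 ± 659.7 in ovary, a log2 fold change of -5.50), MADS29 with -4.88, MADS21 with -4.75 and MADS17 with -4.72. MADS5 had -3.86 and MADS6 -3.54. MADS34 was higher in stigma with 3492 ± 449 in stigma and 276 ± 30.4 in ovary (3.63 in log2). The class B genes MADS16, MADS4 and MADS2, known for stamen and lodicule identity, had 2.27, 1.54 and 1.49, and MADS16 measured 13771 ± 880.3 in stigma and 2853 ± 102 in ovary. DL, which specifies carpels, had 1.42. MADS14 had 1.13, and without ovary replicate 2 its log2 fold change of 0.998 fell short of the fold minimum. MADS58, MADS45 and MADS24 were bright in both tissues, with 21806 ± 1125, 20560.5 ± 848 and 20762 ± 1127 in stigma and log2 fold changes of 0.09, -0.01 and -0.03. MADS1, MADS3, MADS15, MADS18 and FON1 did not pass either, with log2 fold changes of 0.34, 0.07, 0.04, -0.65 and -0.62. As a list they did not pass (adjusted p = 0.802, median log2 fold change 0.01, mean -0.83). Beside the class B genes stand the pollen and anther markers, of which 4 of 14 were higher in stigma and 2 lower.

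**Figure D3:**
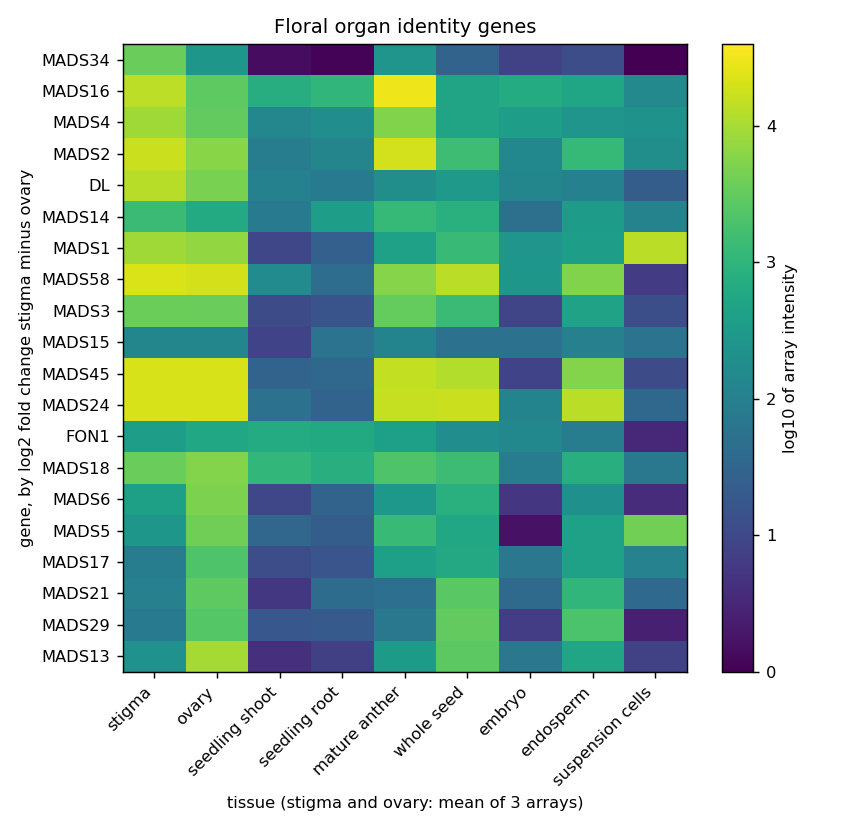
Colour gives the log10 of array intensity of 20 floral organ identity genes (vertical axis) in 9 tissues (horizontal axis), with the mean of 3 arrays for stigma and ovary and 1 array elsewhere. MADS34 read 3492 in stigma and 276 in ovary, whereas MADS13 read 213 and 9707.

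The aim named in the design text was addressed by asking which probe sets were higher in stigma than in each of the 8 other tissues. The other tissues apart from ovary had no replicates, were assumed to vary like stigma and ovary, and grew elsewhere, so that site of growth cannot be told from tissue. Stigma-preferential genes by this rule included LOGL6, with 5290.0 ± 413 (SD, n = 3) and a smallest log2 fold change over the 8 tissues of 4.94, and the auxin-conjugating GH3-1 with 10154 ± 384 and 4.12. MADS34 had a smallest log2 fold change of 3.63, the homeodomain factor gene HOX2 3.32, the mini zinc finger gene MIF4 3.12 and SPX5 2.74. CYP71P1 read 16932 ± 1339 with 2.68, the expansin gene EXP6 11841 ± 462 with 2.63, and BU1, a helix-loop-helix gene induced by brassinosteroid, 23070.1 ± 1444 with 2.62. KCS20, of the enzymes that elongate fatty acids for waxes, read 13794 ± 1171 with 2.56, and PID, of the kinases that steer auxin transport, 7056 ± 248 with 2.44. Hox28 had 2.37, NPR5 2.32, PSY3 2.26, GST-I 2.21 and GT47D 2.20.

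By the rule 639 probe sets were stigma-preferential, 392 of them with exactly 1 gene, for 359 genes, 58 of which had a symbol. At least 8-fold over every other tissue were 84. The next highest tissue was ovary for 215, mature anther for 92, seedling shoot for 90, seedling root for 78, embryo for 59, suspension cells for 45, whole seed for 35 and endosperm for 25. Ovary, measured with as many arrays, had 216 by the same rule and 12 at least 8-fold over every other tissue, MADS6, MADS13 and MADS17 among the 216. The counts for stigma and ovary are not on equal terms, because the panel held tissues closer to ovary. Ovary arrays correlated with the whole seed array by 0.820 to 0.824, and stigma arrays by 0.769 to 0.784. With the anther array the values were 0.731 to 0.734 for ovary and 0.748 to 0.754 for stigma. The number for ovary was 128 under 75th percentile scaling. In 20 simulated data sets with no difference between tissues the limma rule gave at most 0 for either tissue, which does not cover tissues that differ while the 8 contrasts share the stigma arrays. Chalcone synthase was a mixed case, since the brightest CHS1 probe set had a smallest log2 fold change of 0.84 and was not stigma-preferential, while another, read at 10288 in stigma, was.

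Homeodomain transcription factor genes held more stigma-preferential members than the background, 6 of 48 against 342 of 17640 genes, or 1.94%. They were HOX2, Hox28, Hox13, HOX20, WOX8 and GL2-6, named because the count was small and chosen after their values were seen where the naming rule did not reach them. Fisher's exact test, two-sided, gave p = 0.000314 and an adjusted p of 0.0151 over 48 lists. The background held all kept genes, although a symbol list can hold only genes with a symbol. By any probe set, 58 of the 2432 kept genes with a symbol and 359 of all 17640 were stigma-preferential. These p-values may therefore be too small. None of the 12 fixed lists passed this test, and 0 had an unadjusted p under 0.05. The homeodomain call ended with a pseudocount of 0.5 times the table median, without stigma replicate 1 and without ovary replicate 3, where 0 lists passed. Against ovary alone the homeodomain list went both ways, with 10 genes higher and 15 lower, among the latter OSH1 with a log2 fold change of -4.29.

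**Figure D4:**
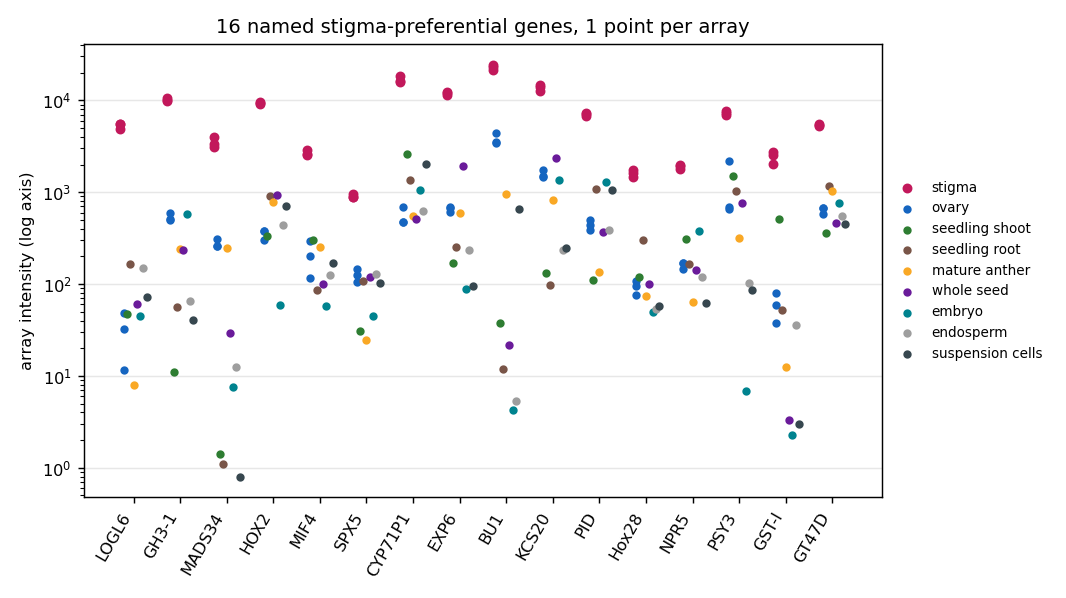
Each point is 1 array's intensity on a log axis for the 16 named stigma-preferential genes, coloured by tissue, with 3 points for stigma and for ovary and 1 for each other tissue. Mean stigma intensity ran from 908 for SPX5 to 23070.1 for BU1.

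Against seedling shoot, photosynthesis genes were lower in stigma and floral genes higher. The size of folds against lone tissues depended on the pseudocount, since 42 of 42 named ones moved by over 1.5 times at 0.5 times the table median and 30 of 42 at a pseudocount of 1. The photosynthesis list had 1 higher and 16 lower of 21 genes and the floral list 19 higher and 0 lower of 20. NAS1, for nicotianamine synthase, read 13.3 ± 15.4 against 20719.8, CFBP1, for chloroplast fructose bisphosphatase, 9.77 ± 6.79 against 14650, and GLK2 3.8 ± 1.71 against 9366. NAS1 had a log2 fold change of -10.30, or -10.89 without stigma replicate 1. Higher in stigma were the response regulator gene RRA14 (7282 ± 507 against 2.9), the sucrose transporter gene SUT5 (15258 ± 1281 against 15.4) and GH3-1 with a log2 fold change of 9.19. In all, 6202 probe sets were higher and 7608 lower.

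Against seedling root, root markers were 0 higher and 22 lower of 25 genes and photosynthesis genes 14 higher and 0 lower of 21. The metallothionein gene MT-I-4c read 8.57 ± 6.18 against 31670.1, NAS1 13.3 ± 15.4 against 28879.6 and the zinc transporter gene ZIP1 3.47 ± 3.51 against 14264. The log2 fold change of NAS1 was -10.78, or -11.37 without stigma replicate 1. BU1 read 23070.1 ± 1444 against 12, the lipid transfer protein gene LTP 20119.9 ± 1376 against 22.4 and MADS24 20762 ± 1127 against 29.5. Higher in stigma were 7114 probe sets and lower 8106, and the root array also carried signals above every other array on 5 control probe sets for a fungus, up to 303.

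Against mature anther, pollen and anther markers were 1 higher and 9 lower of 14 genes. RTS, a tapetum gene, read 20.6 ± 19.4 against 31044, SPPL3 13.5 ± 11.1 against 8959.9 and the expansin gene EXP32 51.2 ± 54.5 against 15278. EXP32 had a log2 fold change of -8.54, with -7.80 without stigma replicate 1 and -9.30 without stigma replicate 3, and SPPL3 had -9.04, with -8.41 without stigma replicate 2. LOGL6 read 5290.0 ± 413 against 7.9, EXLA4 2021 ± 229 against 2.7 and GST-I 2438 ± 354 against 12.5. In all, 7055 probe sets were higher and 7329 lower. Of 635 anther-preferential probe sets, chosen to be low in ovary, 175 were higher in stigma than in ovary and 18 lower, and of 659 chosen without regard to ovary 185 were higher and 26 lower. The median rise was 0.321% of the anther level over all 635 and 0.854% over the 175.

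Against the whole seed, endosperm markers were 1 higher and 15 lower of 18 genes. The glutelin storage protein genes GLUA-1, GLUA-3 and GluC had log2 fold changes of -11.45, -11.17 and -11.17, the last being -12.74 with a pseudocount of 1 and -9.13 with 0.5 times the table median. BU1, the cell wall invertase gene CIN1 and HAK20 had 9.69, 8.52 and 8.10. In all, 6029 probe sets were higher and 6919 lower. Against the embryo, embryo markers were 2 higher and 10 lower of 14 genes and endosperm markers 0 higher and 13 lower of 18. GLUA-1 read 5.3 ± 6.68 against 27212, MFT2 3.07 ± 0.929 against 20485 and the amylase gene AMY1.4 5.07 ± 2.25 against 22332, while MADS45 read 20560.5 ± 848 against 8.3 and BU1 and CIN1 had log2 fold changes of 11.07 and 9.19. With embryo values under the pseudocount, BU1 had 12.09 and CIN1 10.43 with a pseudocount of 1, and 9.31 and 7.30 with 0.5 times the table median. In all, 6137 probe sets were higher and 6331 lower. GLUA-1 also read 56835 on the endosperm array, and the source of the storage protein signal on the lone embryo array was not tested.

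Against the endosperm, endosperm markers were 1 higher and 15 lower of 18 genes and heat shock genes 6 higher and 23 lower of 47. GLUA-1 read 5.3 ± 6.68 against 56835, GluC 1.8 ± 0.557 against 38358 and the allergen gene RA17 6.97 ± 7.5 against 45826, while BU1, SUT5 and CIN1 had log2 fold changes of 10.94, 8.63 and 8.58. In all, 7637 probe sets were higher and 8298 lower, and the actin 3' to 5' ratio of the endosperm array was 12.5. Against suspension cells, cell cycle genes were 9 higher and 56 lower of 94 and photosynthesis genes 16 higher and 1 lower of 21. PDC1, for pyruvate decarboxylase, read 19.3 ± 18.7 against 22106, and the amylase genes AMY1.4 and AMY1.1 had log2 fold changes of -9.69 and -9.51. MADS58 read 21806 ± 1125 against 6.7, and MADS45 and RBOHB, an NADPH oxidase gene, had 10.14 and 10.11. In all, 6891 probe sets were higher and 7215 lower.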

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

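Chosen only after their results were seen were the tests on class B floral genes, on anther-preferential probe sets chosen without ovary, on the number of probe sets under other scalings, and both tests on fungal controls, while the array percentiles had been seen before the scaling test of the split was written. The array carries 10 control probe sets for the rice blast fungus Magnaporthe grisea, which the comparisons do not use, and 5 of them are set out here because they read higher on the seedling root array than on each of the other 12. There the actin controls read 68.7, 182.9 and 221.1 and 2 elongation factor controls read 303 and 149. On the root array 7 of the 10 exceeded 4 times the median of the other arrays, a threshold set after the values were seen, while every other array had 0 or 1. Binding of rice actin RNA to the fungal actin probes is argued against, because the rice actin 3' control on the root array was 1.11 times the median of the other arrays while the fungal actin controls were 5.72 to 16.8 times theirs. RNA of a fungus in the root sample may account for the 7 but cannot be told apart from another root transcript that binds them, since a single root array and no fungal sequence are at hand, and no biological explanation was tested.

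Anther-preferential probe sets, at least 16-fold higher in the anther than in 7 other tissues, leaving stigma aside, were higher in stigma than in ovary for 175 of 635 and lower for 18, a lean that the low ovary level asked of them favours, and for 185 and 26 of 659 chosen with ovary left aside as well. If RNA of whole anthers were carried over into the stigma samples, the brightest anther transcripts would all be raised by a like share. Pollen alone would bring only the transcripts it holds, so unequal shares do not argue against it. The 20 brightest rose by a median of 0.935% of the anther level against 0.854% for the 175, or 0.961% against 0.903% for the 185. The match is partly built in, as 15 of the 20 are themselves called higher. All 635 had a median of 0.321%, and the tapetum gene RTS among the 20 rose by 0.0563%. Shares in the second choice ran from -21.4% for Chia1d to 39.0% for MADS16. Carry-over of whole-anther RNA is argued against for the class B genes, since MADS16, MADS2 and MADS4 would need 39.0%, 82.5% and 260.0% of the anther level, and the share measured was 0.935%. For the other anther-preferential probe sets carry-over may account for part of the rise, and expression in the stigma itself, which the design names as a tissue, stays open and untested.

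The probe sets that differ between stigma and ovary leaned towards lower values in stigma, with 40.3% higher. Array scaling may account for this lean, since the share of higher calls moved by 13.1 percentage points under 75th percentile scaling. The number of calls was 9419 as deposited and 9510 under 75th percentile scaling, a ratio of at most 1.04 over both other scalings. That total says little, because a common shift trades lower calls for higher ones. Of the 9419, 8219 were called in the same direction under 75th percentile scaling and 8292 under quantile normalization. The shared calls were picked for holding under the other scaling, so their holding is no separate evidence on their source. They show only that these calls did not hinge on that choice. The other scalings moved the median log2 fold change by 0.21 and 0.10, and larger or opposite shifts were not tried. Which scaling is right cannot be read from these arrays, because no spiked standard was used here, and a tissue difference in the lean stays open and untested.

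There are 10 splits of the 6 stigma and ovary arrays into 3 and 3, too few for a share under 0.05. For probe sets that differ between stigma and ovary, 1 of the 10 splits gave as many, with 9419 for the real split and 0 as the highest of the others. For stigma-preferential probe sets 1 of 10 did, with 639 and 0, and for ovary-preferential probe sets 1 of 10 did, with 216 and 0. Every other split mixed stigma and ovary arrays in both groups, so the tissue difference added to the spread within groups. A count of 0 was thus favoured beforehand and is no measure of arrays without a tissue difference. For gene lists, 3 of the 10 splits gave as many, with 8 for the real split and 11 as the highest of the others, each of which still set 2 stigma arrays against 1.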

How the results depend on the processing

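The symbol lists, the left-out contrasts and the anther-preferential choice without ovary were chosen after the data files were seen, and the other alternatives before. No gene or list past its threshold changed direction, but the lean of the calls against ovary did under 75th percentile scaling, from 40.3% to 53.4% higher. Counted once per list and setting, gene list tests kept their side of the threshold in 744 cases, gained it in 9 and lost it in 15. Folds of named genes, counted once per fold and setting, kept it in 3818 cases, gained it in 5 and lost it in 101. The 5 gains came without a fold minimum, and 35 of the 101 losses came with the 4-fold minimum, which asks more by itself. Without a fold minimum, 7434 probe sets were higher and 11003 lower in stigma than in ovary, 1299 were stigma-preferential and 944 ovary-preferential, because fewer conditions applied. With a 4-fold minimum these were 1385, 2345, 231 and 45, and stigma differed from seedling shoot in 7827, root in 9028, anther in 7651, whole seed in 6679, embryo in 7058, endosperm in 8941 and suspension cells in 7822. Under 75th percentile scaling 128 probe sets were ovary-preferential, and the cause was not tested. With an estimated correlation, where the test has 4 degrees of freedom, 0 gene lists passed camera. The estimate was 0.00098 for fixed auxin, -0.022 for fixed cell cycle, -0.0095 for Aux/IAA and 0.0059 for symbol heat shock genes. These lie under the preset 0.01, which argues against correlation between genes as the reason that these lists lost their call. The estimate was 0.019 for expansins, 0.051 for photosynthesis, 0.068 for fixed heat shock and 0.208 for symbol cell cycle genes, where the cause was not tested. The list among stigma-preferential genes was lost (0 lists) with a pseudocount of 0.5 times M, without stigma replicate 1 and without ovary replicate 3, and the number ran from 0 to 1 when each replicate was left out. The cause was not tested.

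Leaving out each replicate gave 3504 to 3735 higher, 5244 to 5754 lower, 613 to 653 stigma-preferential, 191 to 226 ovary-preferential and 7 to 10 lists. Stigma-preferential probe sets were 585 with folds alone, where the lowest stigma array had to be at least 2-fold over every array of the other tissues. That asks more than the fold of group means in the main rule. They were 669, 753 and 814 without the endosperm, root or anther contrast. The fixed heat shock list lost its call over 48 lists under 6 settings, with adjusted p up to 0.0885 at preset correlation. A block for the replicate number gave 3682 higher and 5471 lower. Deviations of same-numbered stigma and ovary arrays correlated by 0.016, -0.007 and -0.007, which gave no sign that the numbers pair the samples. Pairing cannot be excluded by this, since the correlations ran over all kept probe sets, dim ones included. Signals near M limit what can be seen, to an extent that was not measured. On each array 45.4% to 54.8% of values lay under M, which follows largely from M being the median of all values.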

Other observations

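These lists and genes were described after the main results were seen, as values with no test chosen for them beyond those of the design. Sugar and cell wall genes included large differences in both directions between stigma and ovary. The cell wall invertase genes CIN1 and CIN2 measured 5527 ± 456 in stigma and 669 ± 87.3 in ovary, and 4008 ± 835 in stigma and 477 ± 102 in ovary, whereas CIN4 had a log2 fold change of -3.08, or -2.44 without stigma replicate 3. CSLA9, of the cellulose synthase-like family, measured 80.5 ± 46.6 in stigma and 3123 ± 168 in ovary, and TBL11 had 4.69. Of 69 cellulose and hemicellulose synthesis genes 21 were higher and 15 lower (camera adjusted p = 0.0933), of 30 sugar transport and sucrose cleavage genes 7 and 8, and of 27 beta-glucosidase genes 3 and 10. ABCG45, an ABC transporter gene, measured 11134 ± 2011 in stigma and 462 ± 69.7 in ovary, and the lipid transfer protein gene LTP 20119.9 ± 1376 in stigma and 1524 ± 182 in ovary. Among lists of 19 lipid transfer, cuticle and wax genes and 15 ABC transporter genes, 5 and 4 were higher and 4 and 3 lower.

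Signalling and transport genes were mixed as well. Of 89 calcium signalling genes 19 were higher and 11 lower (camera adjusted p = 0.0548), with CIPK24, of the kinases bound by calcineurin B-like proteins, at 7217 ± 731 in stigma and 667 ± 93.8 in ovary. The ethylene-forming oxidase gene ACO1 measured 598 ± 206 in stigma and 6188 ± 619.8 in ovary, and the jasmonate synthesis gene AOC3 10733 ± 1073 in stigma and 2050.3 ± 642 in ovary. Higher and lower counts were 8 and 3 of 35 for jasmonate, 8 and 4 of 30 for cytokinin, 1 and 3 of 11 for ethylene, 3 and 3 of 16 for gibberellin, 5 and 4 of 17 for auxin response factors and 8 and 8 of 29 for auxin transport, synthesis and conjugation. NRAMP5, a metal transporter gene, measured 327 ± 127 in stigma and 8425 ± 1016 in ovary, in a list of 83 potassium and cation transport genes with 7 higher and 19 lower. Counts were 2 and 5 of 25 for aquaporins, 1 and 4 of 26 for nitrogen and phosphate transport, 7 and 10 of 42 for Rop GTPases and actin and 3 and 6 of 30 for mitogen-activated and receptor kinases. They were 12 and 9 of 40 for defence proteins, 10 and 7 of 32 for lignin and phenylpropanoid genes, 10 and 11 of 64 for peroxidase and antioxidant genes, 4 and 2 of 25 for abscisic acid and dehydration, and 1 and 1 of 14 for WRKY and NAC factors. Ribosomal protein genes, with 1 higher and 0 lower of 26, passed under quantile normalization only (adjusted p = 0.00478) among the scalings, and as deposited had an estimated correlation of 0.615 and an adjusted p of 0.873 with it. The median, the mean and camera's direction did not share a sign for both floral organ identity lists, small GTPases, and the symbol lists of ethylene, abscisic acid, potassium and cation transport, aquaporins, nitrogen and phosphate transport, ABC transporters, cellulose and hemicellulose synthesis, WRKY and NAC factors and homeodomain factors, and camera passed none of these. Endosperm, embryo and root markers had 0 and 1 of 18, 1 and 3 of 14 and 0 and 5 of 25.

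On the suspension cell array MADS1, a floral gene, read 13044, against 8922 ± 386 in stigma, and MADS5 read 4199.9 there, whereas MADS58 read 6.7. The glutelin gene GLUB-5 read 29076 on the embryo array and 47152 on the endosperm array, and the source of the embryo signal was not tested. An 18S ribosomal RNA control read 2621, 2897 and 289.3 on the 3 stigma arrays and 1498, 275.3 and 464.3 on the 3 ovary arrays. Other ribosomal RNA controls varied less. A second 18S control read 1611.7, 2158.4 and 962 in stigma and 1334.8, 589.3 and 606.7 in ovary. A 28S control read 1776.5, 2012.4 and 512.5 in stigma and 1943.4, 417.3 and 821.7 in ovary. A 25S control read 1187, 970.4 and 735.2 in stigma and 931.8, 750.7 and 1090.6 in ovary. The fungal elongation factor 3' control read 507.7 on the anther array and 505.9 on the root array.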
